A study of Mus musculus with 6 samples.

How the data were processed

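Total RNA was extracted from BMEL hepatoblasts 48 h after transfection with 500 ng of miR-337-3p mimic or of a negative control mimic, and biotin-labelled cRNA was made from 6 ug of it for Affymetrix arrays, per the labels' protocols. There were 6 arrays, 3 per group, and groups and replicate numbers were taken from the sample titles. The array design, the software, the background correction and the normalization are not given in the sources used here.

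The deposited values are 1 log2 signal per transcript cluster and array, for 41345 transcript clusters. They were taken as already normalized by the authors, which the sources used here do not state. Their scale was read from the values, which match the group averages that the authors' comparison table labels as log2. That table has 34472 rows and gives bi-weight averages of the log2 signals per group, a signed fold change, which is a score with no value between -1 and 1, a linear ratio of mimic to control, an ANOVA p-value and an FDR p-value, per the file headers. The deposited ANOVA p-value was checked against an ANOVA recomputed here on the 6 values of each row, and 100% of rows matched within 0.001. The deposited averages lie closer to group medians than to means, with an SD over rows of 0.03 against 0.13 on the log2 scale, so folds computed here from means differ somewhat from the authors'. Neither table gives a detection call, so a low signal may be background, and a fold against it then understates the change.

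Gene symbols came from the authors' comparison table through the transcript cluster ID, which joined 34471 rows. The row left over has a blank ID. It is named Smad3, so this gene was not tested, and the authors' deposited table gives it a ratio of 1.5 and an FDR p-value of 0.238. A further 6874 transcript clusters are not listed in the comparison table, 2003 rows have no symbol and 15 symbols had turned into dates or numbers. The remaining 32453 rows name 30927 genes, of which 909 have several rows, and the row with the highest mean over the 6 arrays was used. Of the symbols, 25464 are current and 1343 are synonyms in the GRCm38.p6 gene table, and 4120 were not matched and keep the file's name. The build behind the array's annotation is not given in the sources used here, so no coordinates are printed. Sequences of 3' UTRs were not used here, and the planned test of genes with a miR-337-3p seed site was not run.

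Differences between the groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither trend nor robust option) on the deposited log2 values, with no filter on dim genes. p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are limma's SEs. The 19 gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and counts are also given adjusted over the list alone. With an estimated correlation in place of the preset one, none of the 7 lists that camera called kept its call. The estimates were -0.0139 for TGF-beta, 0.0206 for Notch and 0.0173 for YAP genes, near the preset 0.01. Correlation hardly accounts for those 3 losses, and limma also uses fewer degrees of freedom in that setting. Estimates were 0.223 for hepatocyte, 0.467 for cholesterol, 0.188 for stress response and 0.488 for cell cycle genes. Tables were handled with data.table (version 1.17.8), pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.

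The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, up to 4 members per list with the smallest unadjusted p, and Afp, Alb, Hnf4a, Onecut1, Sox9, Krt19, Tgfbr1, Tgfbr2, Cdkn1a, Mki67, Mir337, Dlk1 and Meg3. Predicted genes, unnamed loci, receptor gene families (Olfr, Vmn), microRNA and small nucleolar RNA genes, RIKEN clones and pseudogenes are passed over in the lists of largest changes. Some called genes are not reported here. Further lists of intestinal epithelium genes, of matrix and basement membrane genes, and of drug metabolism and bile acid transport genes were written after the largest changes had been seen.

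Groups share replicate numbers 1 to 3, and whether these pair the samples was checked on the data. Deviations from the group means correlated across genes at 0.431, 0.370 and 0.442 between arrays of the same number, and from -0.292 to -0.119 between arrays of different numbers. Deviations within a group cancel out, so the negative values follow from the positive ones and are no separate evidence. With every same-number pair above 0.1, the numbers were taken to pair the samples. The main fit was fixed before this check and models the group alone, with no replicate block. This pairing comes from the values, and the labels do not say that a number marks a shared day. The fit with the replicate number as a block is given where it changes a call or a count by over 1.5 times.

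The fit was tested on simulated data with the mean signals of the 30927 genes and limma's moderated SDs, in 5 simulations of 200 changed genes each. Noise was drawn independently, with no replicate pairs and fewer changed genes than were called here, so rates of recovery may not hold for these arrays. For the comparison of miR-337-3p mimic with control mimic the fit recovered 11.3% of genes changed 1.5-fold, 87.4% of those changed 2-fold and 99.7% of those changed 4-fold, with 8.65% of calls false. An ANOVA with no moderation recovered 0.307%, 0% and 4.72%. Noise drawn at moderated SDs favours a moderated fit, so this contrast does not show which method serves these arrays better. Alternatives covered the variance model, an unmoderated ANOVA, an unadjusted threshold with a 1.5-fold minimum, quantile normalization, median centring, leaving out genes below the 40th percentile of mean signal, the rule for genes with several rows, the replicate block, leaving out each array, an estimated correlation and the fry test. Leaving out both arrays of replicate 1 was added after the array medians were seen.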

Results

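Gene expression was measured on Affymetrix arrays in BMEL cells, an immortalized line of mouse hepatoblasts, which are the fetal liver progenitors of hepatocytes and of cholangiocytes, the cells that line bile ducts. The line came from the liver of wild-type CD1 embryos, and cells were seeded on collagen at 50000 per well. A mimic of miR-337-3p, a microRNA encoded in the imprinted Dlk1-Dio3 region, was transfected into 3 samples and a negative control mimic into 3 others, at 500 ng each and for 48 h. The design compares these groups to find genes whose level differs once miR-337-3p is raised. Median log2 signals over the 30927 genes tested were 4.95, 4.87 and 4.83 in control mimic replicates 1 to 3 and 5.01, 4.85 and 4.84 in miR-337-3p mimic replicates 1 to 3. Pearson correlations across genes, which are not independent replicates, ran from 0.987 to 0.988 among control arrays, from 0.985 to 0.989 among mimic arrays and from 0.975 to 0.985 between the groups. The number of arrays limits the precision, and the median standard error (SE) of a log2 difference was 0.15. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

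The 10 deepest falls after miR-337-3p mimic included 5 enzymes that act on foreign compounds or aldehydes, a bile acid transporter subunit and a hormone of bile acid synthesis. These 10 were not tested as a group. Cyp2c55 (transcript cluster 17359239), a cytochrome P450, fell from 10.27 ± 1.66 to 4.73 ± 0.41 on the log2 scale (SD, 3 arrays per group), a log2 difference of -5.53 with an SE of 0.69, or 46.3-fold (limma, Benjamini-Hochberg adjusted p = 0.00648). The carboxylesterases Ces2a (17504477) and Ces2c fell by 4.45 (SE 0.49) and 3.47 (SE 0.61), the sulfotransferase Sult1d1 by 3.44 (SE 0.49) and the aldehyde dehydrogenase Aldh1a7 by 3.26 (SE 0.53). Slc51b, a subunit of the organic solute transporter that carries bile acids, fell by 3.77 (SE 0.47), and Fgf15, a hormone that restrains bile acid synthesis, by 3.27 (SE 0.33). Complement component C9 fell by 3.80 (SE 0.32), the lectin Clec2e (17471484) by 4.17 (SE 0.64) and the membrane protein gene Ms4a18 by 3.82 (SE 0.51). Their mean signals in the mimic group lay between 4.59 (Ms4a18) and 6.26 (Aldh1a7), where background can add to the signal and folds then understate the change. The Ces2, Cyp2c, Clec2, Aldh1a and Sult families hold close paralogs that a probe set may also read, so the share of each gene within its family is uncertain. Adjusted p-values of these 10 genes in limma ran from 0.00313 (C9) to 0.0218 (Ces2c). The 3 mimic arrays lay below the 3 control arrays for each gene, as the rule for choosing them required. With 1 array left out, 7 of the 10 passed in all 6 fits. Clec2e was lost without control replicate 1 (adjusted p = 0.0655 in limma), Ces2c without control replicate 1 or 3 (up to 0.0917), and Aldh1a7 without control replicate 1 or mimic replicate 1 or 3 (up to 0.0670).

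The largest rises were smaller than the largest falls, and the 10 genes were of mixed function. Klhl1 (transcript cluster 17309024), which encodes an actin-binding protein, rose from 5.23 ± 0.52 to 7.90 ± 0.53 (SD, 3 arrays per group), a log2 difference of 2.68 with an SE of 0.31, or 6.40-fold (limma, Benjamini-Hochberg adjusted p = 0.00566). The leukocyte adhesion molecule Vcam1 (17409649) rose by 2.65 (SE 0.43), the secreted matrix protein osteopontin (Spp1) by 2.42 (SE 0.30), the collagen Col12a1 by 2.15 (SE 0.19) and the membrane skeleton protein Add2 by 2.35 (SE 0.13). Ifi205 (17230111) rose by 2.63 (SE 0.29), the receptor-like phosphatase Ptprn by 2.47 (SE 0.24), the cornified envelope protein involucrin (Ivl) by 2.43 (SE 0.28), the peptidylarginine deiminase Padi2 by 2.22 (SE 0.35) and Fjx1 by 2.09 (SE 0.29). Ifi205 belongs to a family of close paralogs and is uncertain for that reason. Adjusted p-values ran from 8.78e-04 (Add2) to 0.0169 (Vcam1) in limma. The arrays of the groups did not overlap for any of the 10, as the rule for choosing them required. With 1 array left out, 8 of the 10 passed in all 6 fits. Padi2 was lost without control replicate 1 (adjusted p = 0.0712 in limma), and Vcam1 without control replicate 1 or 3 or mimic replicate 2 or 3 (up to 0.0641).

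**Figure D1:**
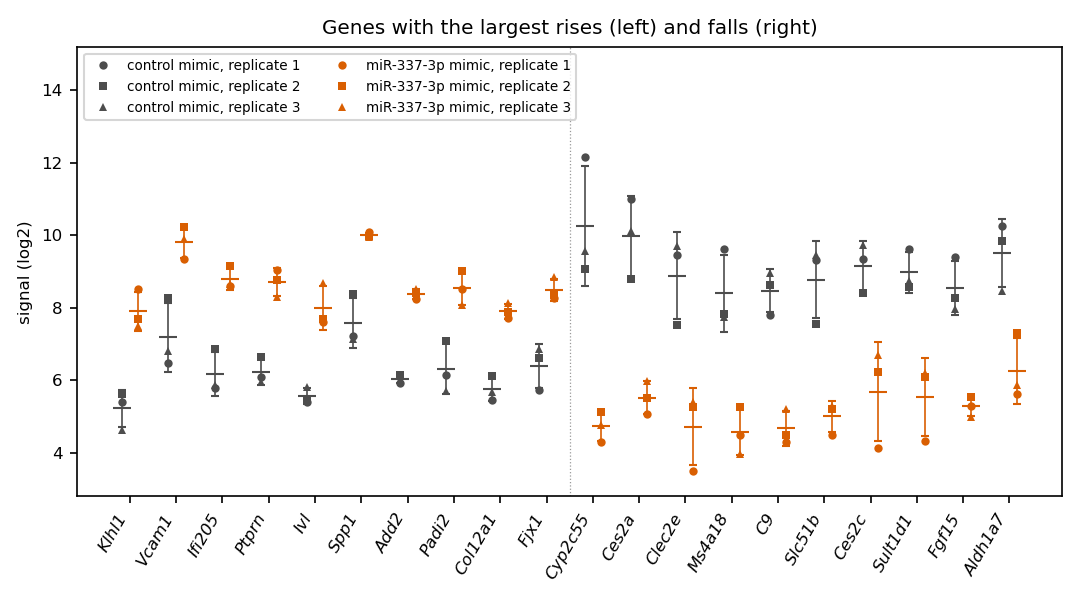
Log2 signal of the 10 genes with the largest rises and the 10 with the largest falls, each array as 1 point, with the group mean and SD as a bar and whiskers, control mimic in grey and miR-337-3p mimic in orange. These genes were chosen among those whose groups did not overlap, and the spread among control arrays was widest for Cyp2c55, with an SD of 1.66.

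In all, 584 genes rose and 519 fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 3.57% of those tested. Falls were deeper than rises, with 307 genes falling and 215 rising at least 2-fold, and 64 falling and 13 rising at least 4-fold. For all 1103 genes the mimic arrays lay on 1 side of the control arrays, which a call with 3 against 3 arrays nearly forces. Over all genes tested 19.6% did so, against 10% by chance. At an unadjusted p under 0.05 there were 4662 genes, where 1546 would be expected with no effect. With the replicate number as a block, 1454 genes rose and 1200 fell, and these held all 1103. Fewer genes passed with any 1 array left out, with fewer arrays as part of the cause. There were 322 without control replicate 1, 721 without control replicate 2, 605 without control replicate 3, and 523, 571 and 563 without mimic replicates 1, 2 and 3. Of the 322, 320 were among the 1103 with the same direction. Without both arrays of replicate 1, whose medians were the highest of their groups, 26 rose and 51 fell, a count chosen after the medians were seen.

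**Figure D2:**
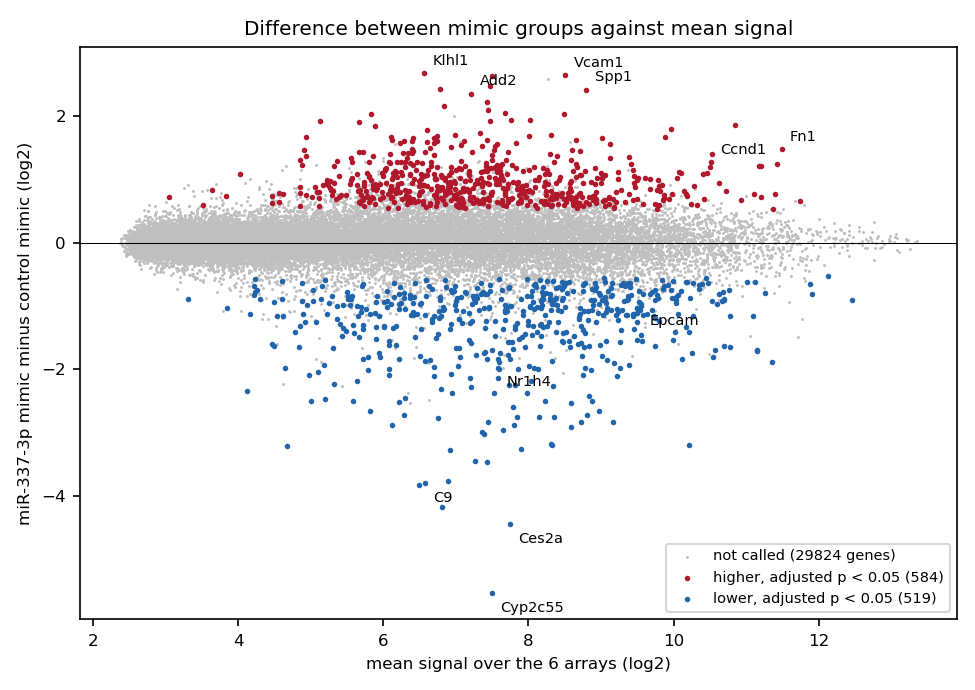
Log2 difference, miR-337-3p mimic minus control mimic, against the mean log2 signal over the 6 arrays, 1 point per gene, with the 584 genes that rose in red, the 519 that fell in blue and the rest in grey. The falls reached -5.53 (Cyp2c55) and the rises 2.68 (Klhl1).

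The array's own row for the microRNA gene, Mir337, read 3.99 ± 0.21 in control and 4.26 ± 0.30 in mimic samples (SD, 3 arrays per group), a log2 difference of 0.27 (SE 0.18, limma adjusted p = 0.596). The row is annotated to the microRNA gene, and whether it can read the transfected duplex is not known here. It is therefore no check of the dose of mimic that entered the cells. Of the 9 genes measured in the Dlk1-Dio3 region, the noncoding RNA gene Rian rose by 0.83 (SE 0.16, adjusted p = 0.0326 in limma), the 1 call both over all genes and adjusted over the list alone. Rian lost that call without control replicate 1 or 3 or mimic replicate 2 or 3 (up to 0.128). Dlk1, a hepatoblast surface protein, read 4.71 in control and 4.88 in mimic samples, a log2 difference of 0.17 (adjusted p = 0.706 in limma). That level is near the medians of the arrays and may be background, so the row can hardly show a fall. The noncoding RNA gene Meg3 had a log2 difference of 0.29 (adjusted p = 0.464 in limma). A dimmer row of Meg3 read 0.68 (SE 0.13) and a dimmer row of Rian 1.24 (SE 0.21). Their unadjusted limma p-values, with every row fitted, were 9.14e-04 and 5.45e-04, against 0.112 for the Meg3 row used above. The rows of Meg3 thus differ, and its change is uncertain. The list's median was 0.19 with an adjusted p of 0.0748 in limma's camera test, which compares a list with all other genes, and 0.0392 without mimic replicate 3.

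Genes that mark liver cell types moved in different directions after miR-337-3p mimic. Of 25 hepatoblast and fetal liver genes, the adhesion protein gene Epcam fell by 1.00 (SE 0.13, adjusted p = 0.00682 in limma) and the imprinted noncoding RNA gene H19 by 1.49 (SE 0.30, adjusted p = 0.0349), while Alcam rose by 0.71 (SE 0.13, adjusted p = 0.0270). Adjusted over the list alone, 2 rose and 4 fell, and 3 rose and 4 fell with the block. Afp, the fetal serum protein, had a log2 difference of -0.39 (SE 0.23, adjusted p = 0.524). The list's mean was -0.06 and its median 0.05, opposite in sign, and camera's adjusted p was 0.679. Epcam passed in every fit that left out 1 array, H19 only in the fit without control replicate 3, and Alcam in none, with adjusted p up to 0.117 for H19 and 0.114 for Alcam.

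Of 37 measured hepatocyte genes, 3 fell and 0 rose over all genes in limma, and 10 fell and 0 rose adjusted over the list alone. At an unadjusted p under 0.05, 10 were lower and 1 was higher. The thyroid hormone carrier Ttr fell by 1.22 (SE 0.22, adjusted p = 0.0259 in limma) and Apob, the protein of lipoprotein particles, by 0.52 (SE 0.11, adjusted p = 0.0465). Albumin (Alb) had a log2 difference of -1.14 (SE 0.34, adjusted p = 0.127, 0.0249 with the block) and the fatty acid carrier Fabp1 -2.48 (SE 0.57, adjusted p = 0.0546, 0.0119 with the block). Camera placed the list lower, at a median of -0.05, with an adjusted p of 0.00503, against an adjusted p of 0.593 with an estimated correlation. With the block 8 members fell. With 1 array left out, Ttr passed only without control replicate 3 (adjusted p up to 0.109) and Apob in no fit that left out an array (up to 0.174).

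Cholangiocyte genes split, with 8 of 30 higher and 3 lower over all genes in limma, and 9 higher and 3 lower adjusted over the list alone. Spp1 rose as given above, the transcription factor gene Sox4 by 1.09 (SE 0.20, adjusted p = 0.0249) and the Notch ligand gene Jag1 by 0.76 (SE 0.13, adjusted p = 0.0193). The bile acid uptake transporter Slc10a2 fell by 2.51 (SE 0.33, adjusted p = 0.00751), the chloride channel Cftr by 2.23 (SE 0.22, adjusted p = 0.00373) and the keratin Krt23, named after its value was seen, by 1.12 (SE 0.22, adjusted p = 0.0320). Sox9 and Krt19, markers of the biliary lineage, had log2 differences of 0.60 (adjusted p = 0.337 in limma) and -0.38 (adjusted p = 0.286). Over the list the median was -0.03 and the mean 0.09, and camera's adjusted p was 0.325, or 0.0333 without control replicate 2. Slc10a2 and Cftr passed without any single array, Sox4 only without control replicate 3 (up to 0.0967) and Jag1 only without control replicate 3 or mimic replicate 2 (up to 0.0832). Sox9, not called with all arrays, passed without control replicate 2 and in no other such fit (up to 0.660 in limma).

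Among 29 liver transcription factors 3 rose and 3 fell in limma, over all genes and adjusted over the list alone. The bile acid receptor gene Nr1h4 (FXR) fell by 1.97 (SE 0.26, adjusted p = 0.00741) and the xenobiotic receptor gene Nr1i2 (PXR) by 1.84 (SE 0.20, adjusted p = 0.00479), both in every fit that left out 1 array. Tcf7l1, a repressor of Wnt targets, rose by 1.26 (SE 0.19, adjusted p = 0.0124) and also passed in every such fit. Sox4 is given above. Nr5a2, at -0.82 (adjusted p = 0.0466), also passed and is named after its value was seen. The hepatic regulators Hnf4a and Onecut1 had log2 differences of -0.35 (adjusted p = 0.271) and -0.36 (adjusted p = 0.302). Camera's adjusted p for these factors was 0.448 at a median of -0.04.

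TGF-beta pathway and target genes were higher on balance after miR-337-3p mimic, with 22 of 35 measured members above 0 and 13 below. Over all genes in limma 5 rose and 0 fell, and 12 rose and 0 fell adjusted over the list alone. At an unadjusted p under 0.05, 14 were higher and 1 was lower, and 10 rose and 1 fell with the block. Fibronectin (Fn1) rose by 1.47 (SE 0.12, adjusted p = 0.00253), the latent TGF-beta binding protein Ltbp1 by 1.27 (SE 0.12, adjusted p = 0.00330), the type I receptor gene Tgfbr1 by 1.21 (SE 0.21, adjusted p = 0.0219) and Id3, an inhibitor of helix-loop-helix factors, by 0.89 (SE 0.17, adjusted p = 0.0318). The fifth, the matricellular protein gene Ctgf, named after its value was seen, rose by 1.36 (SE 0.27, adjusted p = 0.0334). Tgfbr2 had a log2 difference of -0.17 (SE 0.15, adjusted p = 0.718). The list's median was 0.23, with an adjusted p of 0.00112 in camera and an adjusted p of 0.249 with an estimated correlation. Fn1 and Ltbp1 passed without any single array, Tgfbr1 only without control replicate 3 (up to 0.0895) and Id3 only without control replicate 2 (up to 0.105).

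Notch pathway genes were also higher on balance, with 19 of 29 members above 0 and 10 below. Over all genes in limma 5 rose and 0 fell, and 7 rose and 1 fell adjusted over the list alone. At an unadjusted p under 0.05, 10 were higher and 3 lower, and 6 rose and 1 fell with the block. Dtx4, a ubiquitin ligase gene, rose by 1.91 (SE 0.17, adjusted p = 0.00318), the feedback regulator gene Nrarp by 0.93 (SE 0.11, adjusted p = 0.00626), the glycosyltransferase gene Lfng by 1.02 (SE 0.17, adjusted p = 0.0174) and the receptor gene Notch2 by 0.83 (SE 0.13, adjusted p = 0.0126). Jag1, given above, was the fifth. Notch genes had a median of 0.15, with an adjusted p of 0.00648 in camera and an adjusted p of 0.309 with an estimated correlation. Dtx4 and Nrarp passed without any single array, Notch2 was lost without control replicate 1 (0.0644), and Lfng without control replicate 2 or 3 or mimic replicate 1 or 2 (up to 0.0604).

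YAP target genes had 7 of 25 members rising and 1 falling over all genes in limma, and 9 rising and 2 falling adjusted over the list alone. Besides Fjx1 and Ctgf, the angiomotin family gene Amotl1 rose by 0.87 (SE 0.12, adjusted p = 0.00899) and the kinase gene Nuak2 by 0.84 (SE 0.14, adjusted p = 0.0164). Wwc1, which encodes the Hippo pathway scaffold KIBRA, fell by 0.99 (SE 0.16, adjusted p = 0.0145). With the block 10 rose and 3 fell. Of the 25 members, 14 lay above 0 and 11 below. YAP targets had a median of 0.16, with an adjusted p of 0.0398 in camera and an adjusted p of 0.309 with an estimated correlation. That call was also lost without the dimmest genes (adjusted p = 0.118), without control replicate 1 (0.0794), without mimic replicate 2 (0.170) and without both arrays of replicate 1 (0.0545). Fjx1 and Amotl1 passed without any single array, Wwc1 was lost without control replicate 1 (0.0712), and Nuak2 without control replicate 1 or 3 or mimic replicate 2 (up to 0.0669).

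Of 35 Wnt pathway and target genes, 3 rose and 1 fell over all genes in limma, and 5 rose and 1 fell adjusted over the list alone and with the block. Tcf7l1 rose as above, the signal transducer gene Dvl3 rose by 0.95 (SE 0.14, adjusted p = 0.00969), the transcription factor gene Tcf7 rose by 0.96 (SE 0.19, adjusted p = 0.0346), and the R-spondin receptor gene Lgr4 fell by 1.06 (SE 0.13, adjusted p = 0.00626). Lgr4 and Dvl3 passed without any single array and Tcf7 in no such fit (up to 0.0901). Camera's adjusted p for Wnt genes was 0.325 at a median of 0.02. The fry test, which asks whether members move 1 way on balance, gave an adjusted p of 0.0132.

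Cell cycle genes lay higher in the mimic samples as a group, with 39 of 42 members above 0 and a median of 0.48. Cyclin D1 (Ccnd1), which drives entry into the cycle, rose by 1.27 (SE 0.19, adjusted p = 0.0124 in limma), and was lost without control replicate 1 (0.0614). It was the 1 call over all genes, while 4 rose and 1 fell adjusted over the list alone and 7 rose and 1 fell with the block. The replication helicase genes Mcm4 and Mcm7 had log2 differences of 1.18 (adjusted p = 0.0695, 0.0444 with the block) and 0.82 (adjusted p = 0.0513, 0.0399 with the block), and the proliferation marker Mki67 0.84 (SE 0.61, adjusted p = 0.644). Camera's adjusted p for the list was 2.17e-06, against an adjusted p of 0.593 with an estimated correlation. The median differed between replicate pairs, at 1.01, 0.45 and -0.00677 for replicates 1, 2 and 3. Of 29 p53 target and apoptosis genes 0 passed over all genes in limma, 2 rose and 1 fell adjusted over the list alone, 7 were higher and 3 lower at an unadjusted p under 0.05, 0 passed with a trend and robust variance or in an ANOVA, and 4 rose and 3 fell with the block. The cell cycle inhibitor Cdkn1a had a log2 difference of -0.29 (SE 0.15, adjusted p = 0.451), the proapoptotic Bcl2l11 0.71 (adjusted p = 0.0698, 0.0226 with the block), and camera's adjusted p for the list was 0.912 at a median of 0.01.

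Cholesterol synthesis genes fell after miR-337-3p mimic, with 8 of 24 members falling and 0 rising over all genes in limma, and 12 falling and 0 rising adjusted over the list alone. At an unadjusted p under 0.05, 15 were lower and 0 higher. Lanosterol synthase (Lss) fell by 1.06 (SE 0.18, adjusted p = 0.0191), the sterol carrier Stard4 by 0.97 (SE 0.18, adjusted p = 0.0249) and the sterol desaturase Sc5d by 0.83 (SE 0.14, adjusted p = 0.0174). Their median was -0.50 over all arrays, and -0.45, -0.71 and -0.38 in replicate pairs 1, 2 and 3. Camera's adjusted p was 1.57e-11, against an adjusted p of 0.309 with an estimated correlation. Lss and Stard4 were lost without control replicate 1 or 2 or mimic replicate 1 or 3 (up to 0.0818 and 0.107), and Sc5d without control replicate 1 or mimic replicate 1 or 3 (up to 0.0650).

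Genes of the unfolded protein and integrated stress responses lay lower, with 28 of 32 measured members below 0 and a median of -0.32. Of these 0 passed over all genes or adjusted over the list alone in limma, and 0 with a trend and robust variance or in an ANOVA, while 12 were lower and 1 higher at an unadjusted p under 0.05, and 10 fell with the block. The endoplasmic reticulum oxidase gene Ero1l had a log2 difference of -1.48 (adjusted p = 0.0812, 0.0187 with the block), the stress-induced factor Atf3 -1.44 (adjusted p = 0.0913, 0.00215 with the block) and the chaperone partner Dnajb9 -1.18 (adjusted p = 0.0817, 0.00327 with the block). Camera's adjusted p was 2.17e-06, against an adjusted p of 0.309 with an estimated correlation.

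Of 27 measured NF-kB and inflammatory genes, Vcam1 was the 1 that passed in limma, over all genes and adjusted over the list alone. The chemokine Ccl2 had a log2 difference of 2.58 (SE 0.95, adjusted p = 0.231, 0.00674 with the block) and the cytokine Csf2 lay at 5.97 in control and 7.97 in mimic samples (SE of the difference 0.82, adjusted p = 0.293, 0.00191 with the block), since their levels differed widely between replicates of a group. Camera's adjusted p was 0.106 at a median of 0.23, and 9.42e-04 with the block, where 9 rose and 1 fell. It was 2.19e-04 without control replicate 2, 0.00272 without mimic replicate 1 and 0.0372 without both arrays of replicate 1, but 0.694 without control replicate 1, 0.825 without mimic replicate 2 and 0.682 with an estimated correlation. Of 34 interferon response genes Oasl2, a member of a family with close paralogs, rose by 0.78 (SE 0.16, adjusted p = 0.0392 in limma), the 1 call over all genes and adjusted over the list alone, while 3 rose and 2 fell with the block. It passed only without mimic replicate 1 among the fits with 1 array left out (up to 0.143). The list's median was 0.02 and its mean -0.02, and camera's adjusted p was 0.822.

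Markers of other cells that fetal liver holds showed few calls. Of 26 mesenchymal and stellate genes, Zeb1 rose by 0.87 (SE 0.18, adjusted p = 0.0422 in limma) and the collagen Col1a1 by 0.59 (SE 0.12, adjusted p = 0.0384), and the list's median was 0.01 and its mean 0.02, while camera's direction against all other genes was lower (adjusted p = 0.962). Of 27 measured blood, macrophage and endothelial genes, the lysosomal protein gene Cd68 rose by 1.18 (SE 0.23, adjusted p = 0.0320) and Cd34 by 0.88 (SE 0.14, adjusted p = 0.0172), while Ptprc, carried by all leukocytes, lay at 3.22 in control and 3.54 in mimic samples (adjusted p = 0.361). That list's median was -0.01 and its mean 0.05, with a camera adjusted p of 0.943. These counts, 2 per list, stood adjusted over the list alone too, and with the block 2 mesenchymal genes rose and 1 fell. With 1 array left out, Col1a1 passed in no fit (up to 0.118), Zeb1 only without mimic replicate 1 (up to 0.139), Cd68 only without control replicate 2 or mimic replicate 1 (up to 0.115), and Cd34 was lost without control replicate 1 or 3 (up to 0.0724). The replication-dependent histone and mitochondrial genes, read as a sign of RNA quality, had 13 of 27 measured, with 0 passing in limma, 1 falling adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05, 1 falling with a trend and robust variance, 0 in an ANOVA, and a median of 0.05 (camera adjusted p = 0.697). With the block 1 rose and 1 fell. Of 26 microRNA pathway genes, the Argonaute gene Ago1 rose by 0.82 (SE 0.14, adjusted p = 0.0171) and was lost without control replicate 1 or mimic replicate 2 or 3 (up to 0.0804), 2 rose and 1 fell adjusted over the list alone, 4 rose and 1 fell with the block, and camera's adjusted p was 0.219 at a median of 0.11.

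**Figure D3:**
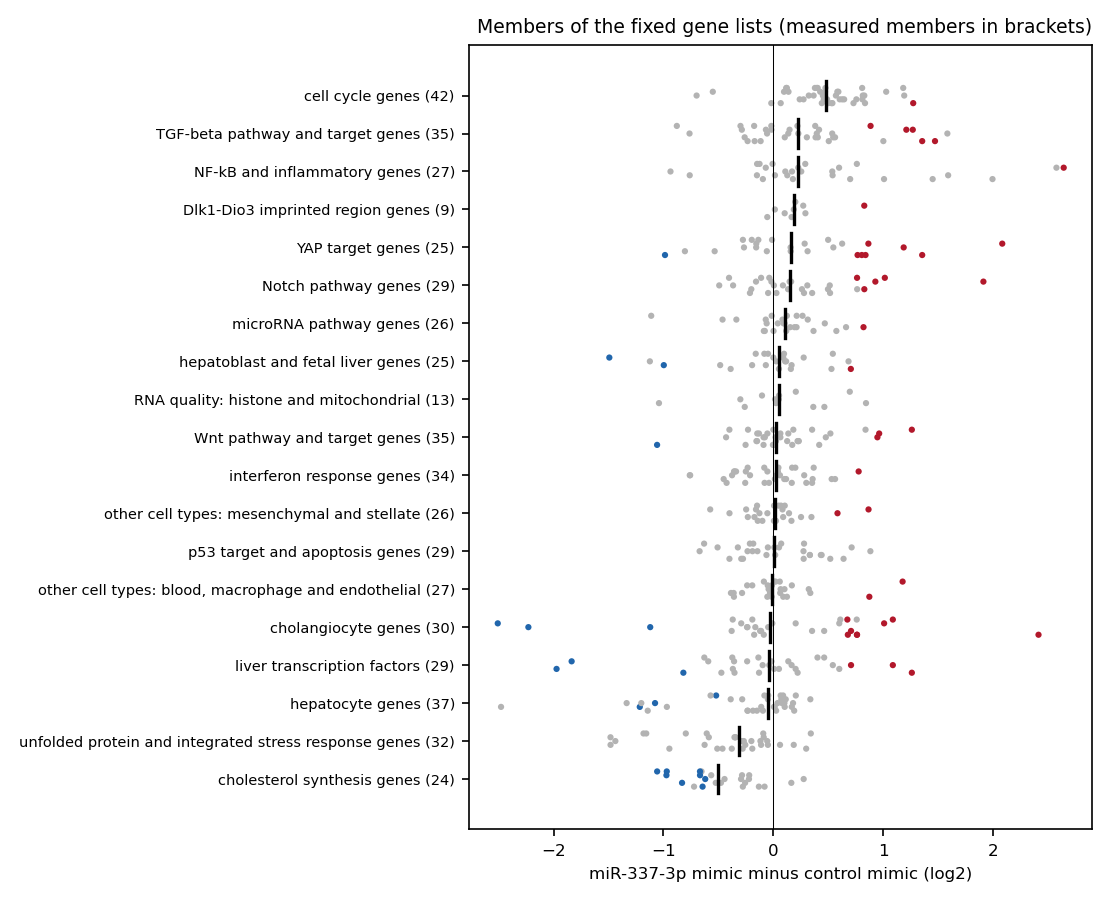
Log2 difference, miR-337-3p mimic minus control mimic, of each measured member of the 19 gene lists, 1 point per gene, red where it rose and blue where it fell at a limma adjusted p under 0.05, grey otherwise, with the list's median as a black bar. Medians ran from -0.50 for cholesterol synthesis genes to 0.48 for cell cycle genes.

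The authors' deposited table gives its own comparison of the same groups. An FDR p under 0.05 is given for 5 genes in the authors' deposited table, and they are named here after their values were seen. Zdhhc1 and Nrarp are higher, with ratios of mimic to control of 2.29 and 1.92 in the authors' deposited table. Lrrc51, Usp12 and Mal2 are lower, with ratios of 0.481, 0.513 and 0.326 in the authors' deposited table. At an ANOVA p under 0.05 and at least a 1.5-fold difference, the authors' deposited table holds 856 higher and 809 lower transcript clusters. The limma fit reported above called Zdhhc1 (log2 difference 1.18), Nrarp (0.93), Lrrc51 (-1.05), Usp12 (-0.91) and Mal2 (-1.57) with the same directions.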

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

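The count in this part was made after the results for named genes were seen. Transcript clusters with no usable gene name lay outside the genes tested, and 23 of the 8892 differed between the mimic groups when every row of the value table was tested together with limma at an adjusted p under 0.05. Of these, 12 were higher and 11 lower in the miR-337-3p mimic samples. The lower ones 17205197 and 17209387 had identical values, so the same signal is counted in both. Transcript cluster 17549918 was lower by 2.71 on the log2 scale (11.20 in control and 8.49 in mimic samples) and 17449332 by 2.24, while 17207837 was higher by 1.26 and 17274385 by 1.13. Adjusted over the 8892 alone, limma called 0, an ANOVA with no moderation called 0, and 980 had an unadjusted limma p under 0.05. No biological explanation was tested, since nothing in the files used here names them. The 8892 include the 6874 that the authors' comparison does not list, and whether these are control probes is not known.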

How the results depend on the processing

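The fit without both arrays of replicate 1 was chosen after the array medians were seen, and every other alternative was planned. Counts of genes that rose and fell (584 and 519 in the report) were 2 and 2 with an unmoderated ANOVA, 1052 and 1014 at an unadjusted p with a 1.5-fold minimum, 242 and 244 with every row tested, 1454 and 1200 with the replicate block, and 26 and 51 without replicate 1 in both groups. With 1 array left out they ran from 150 to 363 and from 172 to 358, with fewer arrays as part of the cause. Median centring gave 351 rising (389 falling), a share of 47.4% rising against 52.9%, and quantile normalization 587 and 653. Counts stayed within 1.5 times with a trend and robust variance, without the dimmest genes and with the mean of a gene's rows.

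With an estimated correlation camera's adjusted p was 0.593 for hepatocyte and cell cycle genes, 0.309 for Notch, YAP, cholesterol and stress response genes, and 0.249 for TGF-beta genes. The fry test lost the hepatocyte and cell cycle lists (0.296 each) and the stress response list (0.145), gained Wnt (0.0132) and Dlk1-Dio3 genes (0.0442), and turned the direction for interferon (0.821) and mesenchymal genes (0.730). Without the dimmest genes YAP targets were lost (0.118), and mesenchymal and RNA quality genes turned direction (0.970 each). The replicate block gained NF-kB genes (9.42e-04) and turned p53 genes (0.985), with no other change in a list's call. Without replicate 1 in both groups YAP targets were lost (0.0545), NF-kB genes gained (0.0372), and p53 and blood genes turned direction (0.753 each). With 1 array left out, adjusted p ranged from 0.0151 to 0.170 for YAP, 2.19e-04 to 0.825 for NF-kB, 0.0333 to 0.573 for cholangiocyte, 0.0392 to 0.225 for Dlk1-Dio3, 0.161 to 0.940 for p53, 0.518 to 0.998 for interferon, 0.699 to 0.951 for mesenchymal, 0.318 to 0.958 for blood and 0.317 to 0.951 for RNA quality genes. Over all lists, the direction turned in 12 results with 1 array left out. The cause was not tested. Quantile normalization and median centring changed no list's call or direction.

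No named gene changed direction. The block brought 26 of the 102 named genes past the threshold and lost none. Median centring lost 7 and quantile normalization 3, and 30 of the 59 called passed without any single array. Seed-site tests were not run for want of 3' UTR sequence, nor were other background corrections or scan batches, with no scanner files used, nor per-array values of the comparison table, which holds averages. Signal over background is unknown.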

Other observations

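The tests in this part that were chosen only after their result was seen are the splits of the arrays, the absence of untransfected cells, the replicate pairs for cell cycle and cholesterol genes, the use of the estimated correlation, which was itself fixed beforehand, to weigh them, and the choice of the 3 further lists. Genes of the intestinal epithelium were lower after miR-337-3p mimic. A list of 42 was written after the 40 largest falls were seen and before these members' values were, and 0 of the 42 are among those 40 or on the other lists. In limma 19 fell and 0 rose at an adjusted p under 0.05, with 24 lower and 0 higher at an unadjusted p. The starch enzyme Mgam fell by 1.97 (SE 0.28), the mucin Muc13 by 1.88 (SE 0.23, from 12.30 to 10.42), the brush border phosphatase Alpi by 1.81 (SE 0.27), the intestinal transcription factor Cdx2 by 1.52 (SE 0.16), villin (Vil1) by 1.13 (SE 0.19) and the galectin Lgals4 by 0.81 (SE 0.12, from 12.31 to 11.51). Krt20, among the brightest at 11.65 in control samples, had a log2 difference of -0.36 (SE 0.13, adjusted p = 0.225).

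Genes of drug metabolism and bile acid transport were lower as well, on a list of 37 written after Cyp2c55, Ces2a, Slc51b, Fgf15, Nr1h4 and Nr1i2 had been seen. In limma 9 of 34 measured fell and 0 rose, 13 fell with the block, and 19 were lower and 0 higher at an unadjusted p under 0.05. Slc51a, the partner subunit of Slc51b, fell by 2.37 (SE 0.31), Cyp4f14 by 1.98 (SE 0.19), Ugt2b34 by 1.71 (SE 0.21) and the efflux pump gene Abcb1a by 1.70 (SE 0.23). The median was -0.61, with a camera adjusted p over the 3 further lists of 2.65e-15 and an adjusted p of 0.0573 with an estimated correlation. Matrix and basement membrane genes did not move as a group. Of 32, 1 rose and 3 fell in limma. Efemp2 rose by 0.60, while the laminin chains Lama3 and Lamc1 fell by 1.28 and 0.66, with 2 rising and 6 falling with the block, and camera's adjusted p was 0.202 at a median of -0.01.

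Several explanations were weighed for the intestinal genes. Members not used to notice the pattern had a median of -0.62 and a camera adjusted p of 1.21e-20, which argues against a pattern held only by the genes it was seen in, though the adjusted p was 0.0506 with an estimated correlation. The pair medians were -0.97, -0.52 and -0.70, the highest being -0.52, which argues against 1 replicate pair deciding it. A smaller share of intestinal-type cells may lower all such genes alike, and all 15 members at 8 or more in control samples were lower, but their log2 differences had an SD of 0.551 against a median SE of 0.196, so this stays open. With 0 arrays of untransfected cells, a rise caused by the control mimic cannot be told apart from a fall caused by miR-337-3p.

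The shift of cell cycle genes differed between replicate pairs. Its lowest pair median was -0.00677, in replicate 3, so not every pair showed it. Growth that differed between replicate numbers, but alike in both arrays of a pair, would cancel within pairs and give no shift. Camera's adjusted p with the replicate block was 1.11e-07. Whether growth differed between the arrays of a pair for reasons other than miR-337-3p was not tested. With an estimated correlation of 0.488, camera's adjusted p for the list was 0.593. Every called list lost its call in that setting, also those with estimates near the preset 0.01. The loss therefore cannot show that correlated members made the preset test's p too small, though they may have. An effect of miR-337-3p on the cycle stays open, as untested beyond these pairs.

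Cholesterol synthesis genes were lower in each replicate pair, the nearest to 0 being -0.38, which argues against a shift carried by some pairs alone. Of 10000 random lists matched on mean signal, 0 had a median as low as -0.50, their lowest being -0.33, which argues against a fall of bright genes as a whole. With an estimated correlation of 0.467, camera's adjusted p was 0.309. Notch and YAP genes, with estimates near the preset 0.01, had the same adjusted p in that setting. It therefore cannot show whether genes that vary together made the preset test's p too small, which stays possible. An effect of miR-337-3p on sterol synthesis is a hypothesis that these arrays leave open.

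The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1103 genes in limma and the highest of the others 0, with up to 2960 genes at an unadjusted p under 0.05 and 0 by an unmoderated ANOVA. It called 7 gene lists and the highest of the others 5. Counting the real split itself, 1 split called that many genes and 1 that many lists, so no other split matched it. Every other split mixes control and mimic arrays on each side, so a group difference adds to the spread within its sides and lowers its calls. The splits therefore cannot tell whether the real split stands out by chance. Among the splits that part all 3 replicate pairs, the others called 0 genes and 3, 1 and 2 lists. The splits that part 1 pair keep a pair together on each side, and called 3 to 5 lists.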
